A study of Mus musculus with 6 samples.

How the data were processed

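RNA was extracted with Trizol 48 h after transfection and 1.3 µg of total RNA went into each library, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCm39, without versions, roles or order. The authors deposited 1 table of FPKM values (fragment counts scaled by gene length and library total), with 16423 gene symbols and 6 columns. Its columns are named con and si with a number, and were matched to the siNC and siYBX1 samples by those names and numbers. No Ucp1 row and no gene of the mitochondrial genome was analysed here. The labels state neither strandedness nor how reads shared between similar genes were counted, so values of paralogs, such as actins, and of genes with many pseudogenes, such as ribosomal protein genes, are uncertain.

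The deposited FPKM values move in steps of 1 read. Each library's total was estimated as a median over 250 to 265 genes whose genomic span matched these steps, and rounded to a whole number. Spans came from an annotation of GRCm38, another build than the one in the processing notes. The totals were 34780658, 34207232 and 35299269 reads for siNC replicates 1 to 3 and 31957411, 35410308 and 33349167 for siYBX1 replicates 1 to 3. For each gene the smallest whole length was then sought that turned all its values into whole reads, with a tolerance of 0.02 reads, and one was found for 16422 of 16423 genes (99.994%). In a test on simulated data 98.8% of 2000 genes were recovered exactly. These were modelled on recovered genes with a mean of at least 10 reads, so the test does not speak for genes with fewer. It used the library totals already found, so it does not test how those were found. Since the smallest length is taken, length and reads both come out too small where a gene's read numbers share a divisor. This is likeliest at few reads but can happen at many. The recovered lengths were used for checks of gene length, and the reads for checks between libraries and for 1 alternative test. Both also served to simulate data for the tests described next. With these totals 1 read on a gene of 2 kb is worth 0.0141 to 0.0157 FPKM, which limits the precision of low values.

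The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the 6 libraries, with no covariate. It was two-sided, and a Benjamini-Hochberg adjusted p below 0.05 was the threshold. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values, while ratios named as fold are ratios of mean FPKM. In a test on simulated data for siYBX1 against siNC, with 10381 genes tested and 50 genes changed at each size, limma recovered 78% of genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 3-fold, and 9 of 193 calls were false. Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01, and adjusted over the 28 of 34 lists with at least 5 tested members. No list was called with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, called 2. The simulated reads were drawn independently for each gene, with 1 dispersion of 0.003 throughout and no trend with gene length. Real genes can differ in spread and the real libraries showed such a trend, so the recovered shares and false calls may be too favourable. In the simulated reads camera called the changed list and 0 of 30 unchanged ones. This does not test lists whose genes move together. In the real data the estimated correlation was 0.743 for respiratory chain, 0.519 for ribosomal protein and 0.447 for G2 and mitosis genes. It was -0.0339 for smooth muscle and myofibroblast genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

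The test, the gene lists, the rule for named genes and all settings not listed next were fixed before the data were examined. Chosen after seeing the data were limma's voom on the recovered reads (genes with a mean of at least 10 reads), a correction for gene length and a correction for GC content. Both corrections subtract a loess curve (span 0.3) of each library's deviations. GC content came from transcripts of GENCODE vM21 matched by symbol, for 98.3% of tested genes. That annotation is of GRCm38, another build than the one in the processing notes, so no coordinates are given. The named genes were Ybx1 with 10 genes of brown fat, adipocytes and mitophagy, whatever their result, the 8 largest rises and the 8 largest falls, and up to 4 members of each list. The largest changes were taken among called genes with a mean FPKM of at least 5 in the higher group and groups that did not overlap, leaving out predicted genes (Gm and Rik symbols) and pseudogenes. Per list these were the 2 largest called rises and the 2 largest called falls, or the 2 most abundant members where none passed. Some genes that this rule takes are not reported here. Other called members of a list with 5 or fewer calls in a direction, and Cdk1, Smtn, Des, Ybx3, Srf, Vcl, Tpm4, Zyx, Cfl1, Actg1 and Actb, were named after their values were seen. Other settings were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-ratio size factors, quantile normalization, rescaling to TPM, limma without a trend, the replicate number as a block, and leaving out each library in turn. Count tests planned for a table of read counts were not run, since the table holds FPKM.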

Results

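C3H10T1/2 is a mouse mesenchymal stem cell line that can be turned into adipocytes. In this series the cells were differentiated with a cocktail that included triiodothyronine and rosiglitazone, transfected on day 4 with a control siRNA (siNC) or with siRNAs against Ybx1 (siYBX1), and harvested 48 h later for RNA sequencing. YBX1 is a cold-shock domain protein that binds RNA and DNA. There were 3 libraries per group, and the deposited values were FPKM for 16423 gene symbols. Whole reads could be recovered from these values, and the library totals were 34207232 to 35299269 reads for siNC and 31957411 to 35410308 reads for siYBX1. Of each total 99.36% to 99.42% lay on the table's genes. The totals are thus those behind the FPKM values and do not give the number of reads sequenced. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

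The comparison of siYBX1 with siNC asks which transcripts differ in these differentiated cells, which the submitters call brown adipocytes, after Ybx1 is reduced. Ybx1 mRNA fell from 133 ± 2.98 FPKM (SD, n = 3) in siNC to 62.9 ± 4.50 FPKM (SD, n = 3) in siYBX1, which left 47.3% of the control level. Its log2 fold change was -1.07 (SE 0.06, adjusted p = 3.98e-06, limma), with a 95% confidence interval of -1.20 to -0.94. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. Among 10341 genes tested, 2132 (20.6%) passed the threshold, 987 higher and 1145 lower in siYBX1. Without siYBX1 replicate 1 the count was 1199 and without siYBX1 replicate 2 it was 1306, and without siNC replicate 3 there were 750 lower calls. Most of these changes were small. The median absolute log2 fold change of the called genes was 0.288, 191 of them reached 0.5, and 15 reached a doubling or halving (12 higher and 3 lower). The groups did not overlap for 40.9% of tested genes, against 10% by chance. The share of calls that were higher was 46.3%, and 29.6% (662 higher, 1573 lower) when each library was rescaled to TPM.

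**Figure D1:**
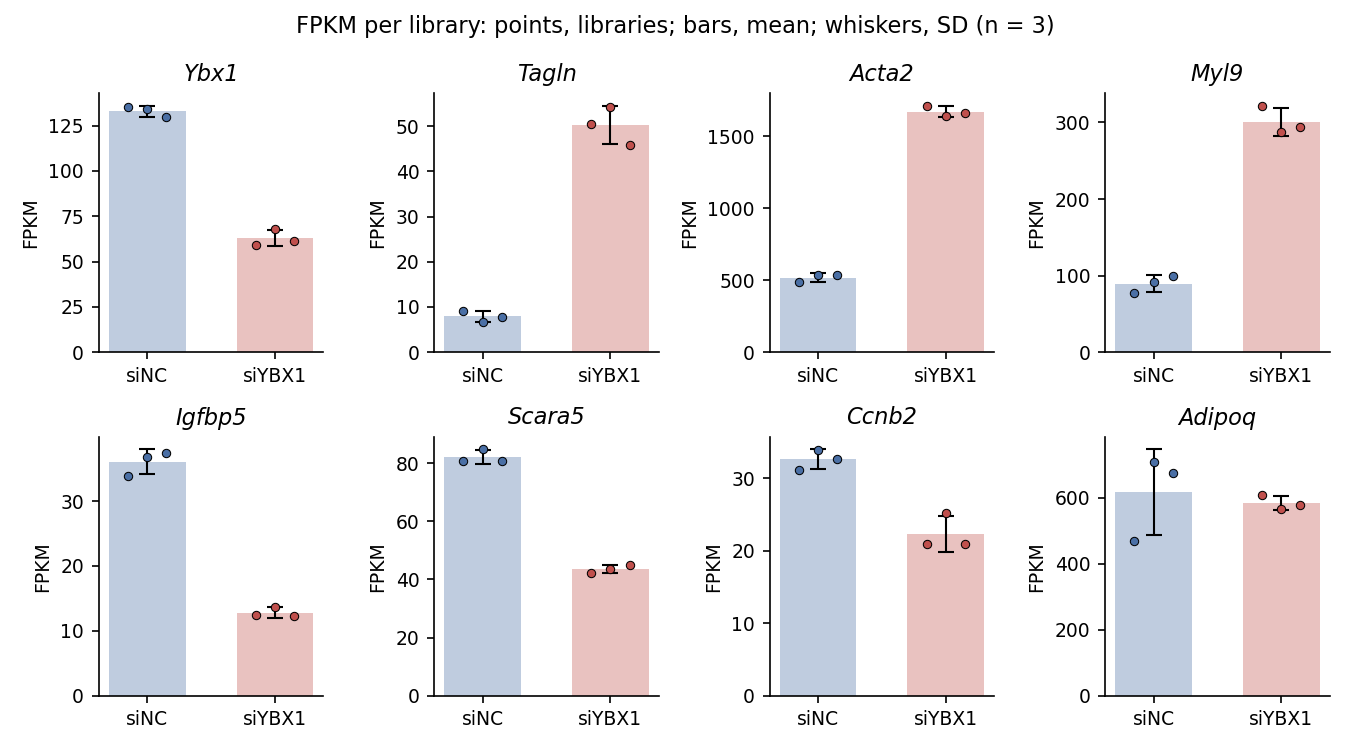
FPKM (vertical axes, starting at 0) of 8 genes in siNC and siYBX1 libraries. Points are libraries, bars are group means and whiskers are SD (n = 3 per group). Ybx1, Igfbp5, Scara5 and Ccnb2 lie lower in every siYBX1 library than in any siNC library, Tagln, Acta2 and Myl9 lie higher, and the Adipoq values of the groups overlap.

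Genes of the contractile apparatus were among the largest rises. Of 9 tested genes in the smooth muscle and myofibroblast list, 7 rose and none fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.94. Tagln, which encodes the actin-binding protein transgelin, rose from 7.90 ± 1.24 to 50.3 ± 4.24 FPKM (SD, n = 3 each), a 6.37-fold difference in means (log2 fold change 2.53, SE 0.10, adjusted p = 2.61e-07, limma). The smooth muscle actins Actg2 and Acta2 were 4.34-fold and 3.23-fold higher. Acta2 was already abundant in control cells, at 518 ± 29.7 FPKM, and reached 1671 ± 35.7 FPKM. Myl9, a regulatory light chain of myosin, was 3.36-fold higher, from 89.6 ± 10.9 to 301.0 ± 18.2 FPKM. Smtn (log2 fold change -0.11, adjusted p = 0.283, limma) and Des (-0.13, adjusted p = 0.416) did not pass. The camera test of the list gave an adjusted p of 1.74e-09, against an adjusted p of 0.0752 with an estimated correlation. Actin genes are similar in sequence, and the deposited values cannot show how reads shared among them were assigned. The skeletal muscle actin Acta1, 1 of 2 tested genes of the skeletal muscle list, rose from 0.447 ± 0.226 to 2.24 ± 0.779 FPKM (adjusted p = 0.00144, limma). Des was the other.

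Outside the 2 muscle lists, and among genes with a mean of at least 5 FPKM in the higher group, the largest rises were those of Ccn2, a matricellular protein (2.85-fold), Lims2, a focal adhesion adaptor (2.80-fold), Nexn, an actin-binding protein (2.65-fold), and Ptgs2, the inducible cyclooxygenase (2.26-fold). Their adjusted p-values ran from 6.56e-06 for Nexn to 0.000263 for Lims2 (limma). Igfbp5, which binds insulin-like growth factors, fell most, from 36.1 ± 1.92 to 12.8 ± 0.799 FPKM (log2 fold change -1.42, SE 0.06, adjusted p = 4.66e-07, limma). Scara5, a ferritin receptor, fell from 82.1 ± 2.30 to 43.6 ± 1.41 FPKM. Complement C3 fell from 90.3 ± 8.42 to 50.3 ± 1.77 FPKM, and the metalloproteinase inhibitor Timp2 from 194 ± 4.78 to 109 ± 5.07 FPKM. Kctd12 and Igsf10 had log2 fold changes of -0.80 and -0.78, with adjusted p-values of 0.000244 and 0.000199. LOC118567384, an uncharacterised locus, fell from 16.5 ± 1.11 to 7.95 ± 4.72 FPKM (adjusted p = 0.0292, limma), a call that was lost without siNC replicate 2 or without siYBX1 replicate 2. Without siYBX1 replicate 3 its log2 fold change went from -1.13 to -0.65.

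Cell cycle genes were lower in siYBX1. In the G2 and mitosis list 27 of 28 genes fell (28 adjusted over the list alone), with log2 fold changes between -0.53 and -0.17 and a median of -0.40. Ccnb2, a mitotic cyclin, fell from 32.6 ± 1.37 to 22.3 ± 2.50 FPKM (adjusted p = 0.00109, limma), and Cdc20, an activator of the anaphase-promoting complex, from 27.8 ± 0.715 to 19.1 ± 2.41 FPKM (adjusted p = 0.00182). Cdk1 was the exception, at -0.17 (adjusted p = 0.0813), and passed without siYBX1 replicate 2 (adjusted p = 0.0449). In the DNA replication and S phase list 14 of 25 genes fell (17 adjusted over the list alone), with a median of -0.21, but 8 fell without siYBX1 replicate 1 and 9 without siYBX1 replicate 3. Rrm2, a subunit of ribonucleotide reductase, had a log2 fold change of -0.67 and Uhrf1, which takes part in maintaining DNA methylation, -0.66. Camera adjusted p-values were 3.22e-18 for G2 and mitosis and 1.04e-06 for S phase. Neither call held with an estimated correlation (adjusted p = 0.659 and 0.774). Among replication-dependent histone genes 1 of 9 tested passed (2 adjusted over the list alone), the linker histone gene H1f4 (log2 fold change -0.44, adjusted p = 0.0148, limma), and the list did not pass (adjusted p = 0.402, camera).

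Genes for ribosomal proteins and the respiratory chain were slightly higher. Of 79 cytosolic ribosomal protein genes 13 rose and none fell (6 adjusted over the list alone), 76 had a positive log2 fold change, and the median was 0.17. Rpl29 rose from 22.1 ± 1.75 to 29.1 ± 5.84 FPKM and Rps7 from 300.0 ± 10.9 to 378 ± 39.7 FPKM. Of 77 nuclear genes for the respiratory chain and ATP synthase 15 rose and none fell (15 adjusted over the list alone), with a median of 0.19. The complex I subunit genes Ndufa5 and Ndufv2 had log2 fold changes of 0.38 and 0.36. Camera adjusted p-values were 1.74e-09 and 2.58e-08, and 0.774 for both with an estimated correlation. These genes are short, and short genes as a whole were higher in siYBX1. The median log2 fold change was 0.078 in the shortest 20% of tested genes and -0.067 in the longest 20%. Of the tested ribosomal protein genes 87.3% lay among the shortest, and of the respiratory chain genes 84.4%. Among all genes of the shortest 20%, 18.9% were called higher and 6.23% lower. Both lists' counts of rises lie near that share of higher calls. After a correction for length the medians were 0.051 for ribosomal protein genes (adjusted p = 0.141, camera) and 0.075 for respiratory chain genes (adjusted p = 0.0450). Then 5 ribosomal protein genes rose and 1 fell, and 6 respiratory chain genes rose and 4 fell. With quantile normalization the medians were 0.081 and 0.097. There 8 ribosomal protein genes rose and 1 fell, and 9 respiratory chain genes rose and 4 fell. Leaving out siNC replicate 1, which differed from the other control libraries by a chi-square per gene of 19.9 to 23.2 against 4.64 between those libraries, gave medians of 0.12 and 0.11, and 9 respiratory chain genes then rose and 2 fell. Without siYBX1 replicate 1, 2 ribosomal protein genes and 3 respiratory chain genes passed. Without siYBX1 replicate 2 these counts were 3 and 6, and without siNC replicate 3 they were 3 and 10. They were higher, at 19 and 20, without siYBX1 replicate 3, and 28 and 25 with voom on recovered reads. Rpl29 was at 0.22 without siYBX1 replicate 1, against 0.37.

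**Figure D2:**
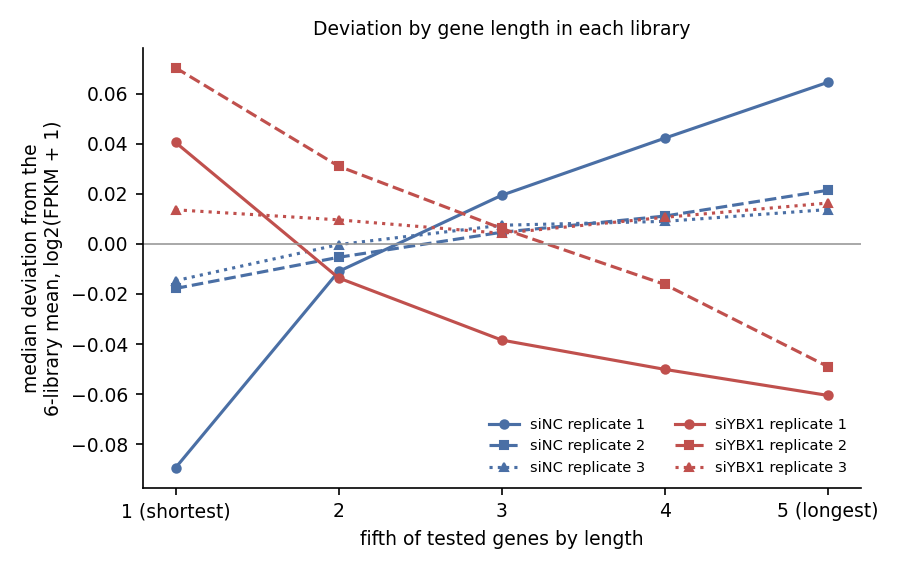
Median deviation of each library from the mean of the 6 libraries, in log2(FPKM + 1) (vertical axis), for 5 equal bins of tested genes from shortest to longest (horizontal axis). Lines are the 6 libraries, blue for siNC and red for siYBX1. siNC replicate 1 has short genes lower than long ones (difference -0.154), siYBX1 replicates 1 and 2 have them higher (0.101 and 0.119), and siYBX1 replicate 3 shows almost no slope (-0.0028).

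Of 24 thermogenic and brown adipocyte genes with values only 8 were abundant enough to test, and none of these passed (0 adjusted over the list alone). The lack of calls therefore says little about the rest of that list. Cox8b was 113 ± 16.7 FPKM in siNC and 134 ± 36.2 FPKM in siYBX1 (adjusted p = 0.333, limma), and Cidea, a lipid droplet protein of brown fat, 21.2 ± 2.08 and 19.6 ± 2.83 FPKM (adjusted p = 0.447). Ppargc1a, the coactivator of mitochondrial biogenesis, Dio2, which activates thyroid hormone, and Prdm16, a regulator of brown fat identity, lay below the filter, at 0.729, 0.244 and 0.0020 FPKM in siNC. Without a filter their adjusted p-values were 0.126, 0.249 and 0.939. Ucp1 was not analysed here. Of 22 general adipocyte genes 2 rose and 3 fell (2 and 5 adjusted over the list alone). Without siNC replicate 1, 8 fell (median -0.13, adjusted p = 0.0858, camera). None rose without siYBX1 replicate 1 or without siYBX1 replicate 3, and 1 rose without siNC replicate 3 or without siYBX1 replicate 2. With TPM 1 rose and 7 fell, and with quantile normalization 2 rose and 6 fell. Plin2, a lipid droplet coat protein, rose from 419 ± 52.3 to 523 ± 24.3 FPKM (adjusted p = 0.0250). Pnpla2, the triglyceride lipase ATGL, fell from 402 ± 28.9 to 297 ± 9.93 FPKM (adjusted p = 0.00189, limma), Cfd had a log2 fold change of -0.32 and Plin4 -0.26. Pparg (0.08, adjusted p = 0.389), Adipoq (-0.06, adjusted p = 0.783) and Fabp4 (0.26, adjusted p = 0.209) did not pass. Without siNC replicate 1, in which Adipoq was lower than in the other controls, Adipoq passed at -0.25 (adjusted p = 0.0130) and Fabp4 was at 0.08 (adjusted p = 0.567). Camera gave adjusted p-values of 0.772 for the thermogenic list and 0.621 for the general one. None of 4 tested white or beige adipocyte genes passed (0 adjusted over the list alone), among them Rb1 (-0.10) and Ednra (-0.16).

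**Figure D3:**
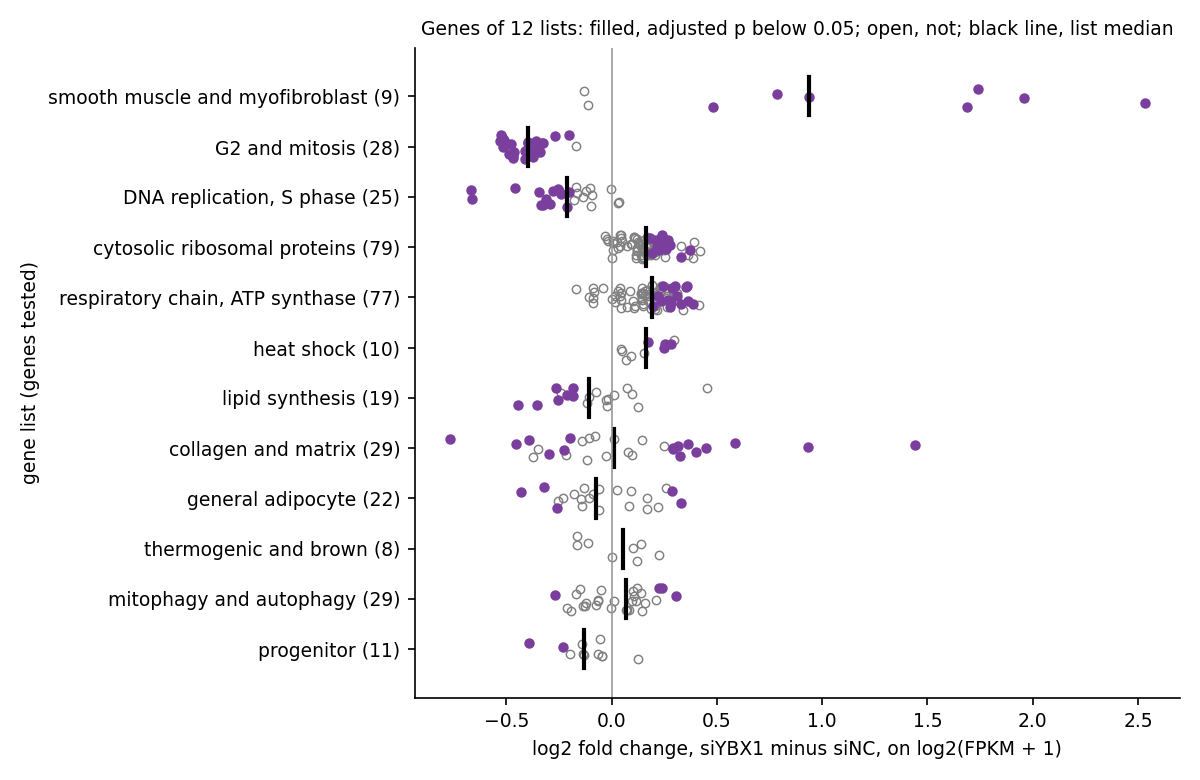
Log2 fold change, siYBX1 minus siNC, on the log2(FPKM + 1) scale (horizontal axis) for each tested gene of 12 lists (vertical axis, with the number of genes tested). Filled points passed the threshold, open points did not, and black lines are list medians. The smooth muscle list has its median at 0.94 and the G2 and mitosis list at -0.40, while the thermogenic list has no filled point.

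In the mitophagy and autophagy list 3 of 29 genes rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.454, camera). Without siYBX1 replicate 1, 1 rose. Atg12, a ubiquitin-like protein of autophagosome formation, rose from 65.6 ± 2.46 to 81.4 ± 3.50 FPKM, and the ATG8-family genes Map1lc3a and Gabarapl2 had log2 fold changes of 0.24 and 0.22. Lamp2, a lysosomal membrane protein, fell from 83.0 ± 4.50 to 68.6 ± 1.56 FPKM. Pink1, the kinase that starts mitophagy on damaged mitochondria, was 36.3 ± 1.32 FPKM in siNC and 32.5 ± 0.944 FPKM in siYBX1 (log2 fold change -0.15, SE 0.05, adjusted p = 0.0621, limma), and passed with TPM (adjusted p = 0.0298), with quantile normalization (0.0385) and after the length correction (0.0438). Among 26 genes of mitochondrial dynamics and biogenesis Fis1 rose, and Tfb2m, Polrmt and Opa1 fell, with log2 fold changes of 0.24, -0.30, -0.27 and -0.24 (1 and 3 adjusted over the list alone; adjusted p = 0.654, camera). Genes coded in the mitochondrial genome were not analysed here.

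Of 19 fatty acid and triglyceride synthesis genes 7 fell and none rose (8 adjusted over the list alone), but the list did not pass (median -0.11, adjusted p = 0.0582, camera). It passed without siNC replicate 1 (adjusted p = 0.00679) and without siYBX1 replicate 1 (adjusted p = 0.00617). Only 2 genes fell without siNC replicate 3 (adjusted p = 0.226) or without siYBX1 replicate 2 (adjusted p = 0.116), and 4 without siYBX1 replicate 3 (adjusted p = 0.185). Lpin1, a phosphatidate phosphatase, fell from 15.7 ± 1.51 to 11.2 ± 0.115 FPKM. Scd1, the stearoyl-CoA desaturase, fell from 2472 ± 140.0 to 1931 ± 132 FPKM. In the fatty acid oxidation list 1 of 23 genes passed (1 adjusted over the list alone), Echs1 (log2 fold change -0.38). Its median was 0.017, its mean -0.0030 and its camera direction upward, with an adjusted p of 0.961. Among 24 cholesterol synthesis genes Lss, Tm7sf2 and Hsd17b7 fell (-0.30, -0.29 and -0.18, 3 adjusted over the list alone, adjusted p = 0.816 for the list, camera). Of 17 glycolysis genes Hk2 and Gpi1 fell, at -0.43 each (1 adjusted over the list alone, adjusted p = 0.181 for the list, and 0.0221 without siNC replicate 2). Gpi1 was at -0.24 without siNC replicate 1. Neither passed without siYBX1 replicate 1, and 1 gene of the list fell without siYBX1 replicate 2 or without siYBX1 replicate 3. Of 18 branched-chain amino acid breakdown genes Bckdha and Pccb fell (-0.21 and -0.20, 2 adjusted over the list alone). That list's median was 0.0015, its mean -0.0039 and its camera adjusted p 0.961, with a downward direction.

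Extracellular matrix genes changed in both directions. Of 29 tested, 10 rose and 6 fell (11 and 8 adjusted over the list alone), with a camera adjusted p of 0.402. Without siNC replicate 3 or without siYBX1 replicate 1, 3 fell. Ccn2 was among those that rose. Fbn1, the microfibril protein fibrillin 1, fell from 19.5 ± 0.583 to 11.03 ± 0.565 FPKM, and Col3a1 from 576 ± 15.9 to 420.3 ± 9.50 FPKM. In the preadipocyte and mesenchymal progenitor list 2 of 11 genes fell and none rose (2 adjusted over the list alone; median -0.13, adjusted p = 0.134, camera), namely Eng (-0.39) and Cd44 (-0.23). In the osteoblast list Dmp1 and Runx2 fell (-0.51 and -0.39, of 6 tested, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.402). Sox9, the only tested gene of the chondrocyte list, fell by 0.32 on the log2 scale (adjusted p = 0.0449, limma), a call lost without siNC replicate 1 (-0.20) and without each siYBX1 library in turn. None of 3 tested macrophage and leukocyte genes passed (1 lower adjusted over the list alone), among them Cd68 (-0.69, adjusted p = 0.0681) and Cd14 (0.05). Without siNC replicate 1 Cd68 was at -0.35 (adjusted p = 0.110), and it passed without siNC replicate 2 (-0.91, adjusted p = 0.0216). Egfl7, the only tested endothelial gene, was at -0.18 (adjusted p = 0.190) and passed without siNC replicate 1 (-0.29, adjusted p = 0.00864).

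Among stress and signalling lists the heat shock list passed (4 of 10 genes rose, none fell, 5 adjusted over the list alone, median 0.16, adjusted p = 0.00756, camera), with an adjusted p of 0.774 with an estimated correlation. The count was 1 without siYBX1 replicate 1 or without siYBX1 replicate 2, and 2 without siNC replicate 2 or without siNC replicate 3. The called genes were the chaperone genes Hsp90aa1 (0.28), Hsph1 (0.25), Dnaja1 (0.25) and Hspb8 (0.17). In the inflammatory and chemokine list Ptgs2, Ccl7 and Csf1 rose (1.06, 0.44 and 0.36) and Cxcl12, Tnfaip3 and Relb fell (-0.61, -0.31 and -0.25), of 14 tested (4 and 3 adjusted over the list alone). Tnfaip3 was at -0.19 without siNC replicate 1. This list's median was -0.033, its mean 0.030 and its camera adjusted p 0.961, with an upward direction. Of 20 interferon response genes Gbp2 and Gbp3 rose (0.39 and 0.34) and Irf7, Ifi44 and Ifit2 fell (-0.29, -0.25 and -0.21, 4 and 3 adjusted over the list alone, adjusted p = 0.621 for the list). Of 13 immediate early genes Dusp1, Myc and Zfp36 rose (0.46, 0.35 and 0.31) and Egr1 and Nr4a1 fell (-0.36 and -0.31, 3 and 2 adjusted over the list alone, adjusted p = 0.654). Of 19 p53 targets Plk2 and Cdkn1a rose (0.39 and 0.18, 1 adjusted over the list alone, adjusted p = 0.961). In the integrated stress and unfolded protein response list Ddit3, Vldlr and Creld2 fell (-0.35, -0.35 and -0.20, of 25 tested, 3 adjusted over the list alone, adjusted p = 0.972). In the NRF2 target list Srxn1, Gsr and Txnrd1 rose (0.34, 0.23 and 0.18) and Tkt fell (-0.41, of 19 tested, 3 and 1 adjusted over the list alone, adjusted p = 0.181).

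Lists built around YBX1 itself did not pass. Among 19 cold-shock domain proteins and messenger ribonucleoprotein partners Igf2bp2, Fxr1 and Ybx3 rose (0.34, 0.29 and 0.22) and G3bp2 fell (-0.19, 3 and 1 adjusted over the list alone, adjusted p = 0.348, camera). Of 20 tested genes that earlier work has tied to YBX1, 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.402). They included Col1a1 (0.36) and Hif1a (0.27), and the cyclin genes Ccnb1 (-0.48) and Ccna2 (-0.40), which also stand in the G2 and mitosis list. Among 15 translation factor genes with a 5' terminal oligopyrimidine tract Eif3e and Npm1 rose (0.30 and 0.22) and Eef2 fell from 1036 ± 44.7 to 805.5 ± 17.4 FPKM (2 and 1 adjusted over the list alone, adjusted p = 0.287 for the list). Of the 103 named genes past the threshold, 52 lost their call under at least 1 other setting, and 44 of these did so when a single library was left out. They included LOC118567384, Plin2, Cfd, Map1lc3a, Ndufa5, Ndufv2, Fis1, Polrmt, Scd1, Tm7sf2, Hk2, Gpi1, Bckdha, Pccb, Cdkn1a, Gbp3, Irf7, Ifi44, Ccl7, Tnfaip3, Hsph1, Egr1, Nr4a1, Gsr, Eng, Sox9, Rpl29, Npm1, H1f4, G3bp2, Ybx3, Actg1, Actb, Plin4, Gabarapl2, Opa1, Hsd17b7, Ifit2, Relb, Creld2, Dnaja1, Hspb8 and Txnrd1.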

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

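The voom test and the length and GC corrections were chosen after the data were seen. No called gene turned direction and stayed past the threshold in any setting, and no called list did. Ybx1 kept its call in all 18 alternatives, with log2 fold changes between -1.16 and -1.03. Without a filter on low values 1241 genes passed (577 higher, 664 lower), with 16423 genes tested. With the replicate number as a block 1346 passed (607 higher, 739 lower). The labels do not say whether the numbers pair the samples. Same-numbered libraries' deviations correlated at -0.306, -0.131 and -0.246 across genes, and 0 of 3 control libraries correlated best with its own number. These values show no sign of pairing, but 3 libraries per group cannot exclude it. Leaving out 1 library gave 1199 to 2026 calls, 547 to 970 of them higher and 604 to 1056 lower. The total was lowest without siYBX1 replicate 1 (1199) and 1306 without siYBX1 replicate 2, and without siNC replicate 3 there were 750 lower calls. Fewer libraries give less power, and the cause beyond that was not tested. Calls with at least a doubling or halving numbered 26 with a pseudocount of 0.1 and 81 with voom on recovered reads (1065 higher and 1398 lower calls in all), since a smaller pseudocount shrinks low genes less and voom adds less to low genes and tested 12177 genes. Lower calls outnumbered higher ones with the main settings, but the balance turned with median-ratio size factors (1142 higher, 968 lower) and with a mean FPKM of at least 5 (936 higher, 863 lower). Medians of several lists that did not pass changed sign, as for general adipocyte genes (-0.133 to 0.0119).

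The number of lists past the threshold was 0 with an estimated correlation, where the lowest adjusted p was 0.0752, for the smooth muscle list. Fry called 2, smooth muscle (5.13e-05) and G2 and mitosis (0.0113). The other settings called 6 to 8 lists. The ribosomal protein list lost its call after the length correction, and the histone list gained one there. The fatty acid and triglyceride synthesis list passed with a mean FPKM of at least 5, with quantile normalization, with TPM and without siNC replicate 1 or siYBX1 replicate 1 (adjusted p from 0.00418 to 0.774 over its alternatives). The glycolysis list passed with quantile normalization and without siNC replicate 2 (adjusted p from 0.0130 to 0.966 over its alternatives). Of the 103 named genes past the threshold 51 kept their call in every alternative that tested them and 58 did so with the unfiltered test set aside. Quantile normalization moved the log2 fold changes of Actb, Actg1, Cdkn1a, Col1a1, Eif3e, Hsp90aa1, Npm1, Rps7 and Ybx3 by over 1.5 times, and the length correction those of Fis1, Gabarapl2, Map1lc3a and Ndufa5. Acta1, a low gene, was at 2.13 with a pseudocount of 0.1 and 2.41 with voom. Relb, also low, was at -0.25 in the main test, -0.44 with a pseudocount of 0.1, -0.39 with TPM and -0.49 with voom. Cd68 passed with TPM and with voom, and Cdk1 with TPM. Prdm16 had under 1 read per library on average, so no change can be read from it.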

Other observations

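The 3 held-out lists, and the tests on adipocyte share, actin paralogs and serum response factor targets, were chosen only after the largest changes had been seen. Of 25 tested targets of serum response factor and its MRTF coactivators, none of them in the lists described so far, 16 rose and 1 fell, with a median log2 fold change of 0.40. The list passed with camera's preset correlation (adjusted p = 4.57e-13) and did not with an estimated correlation (adjusted p = 0.0602). Srf itself rose from 11.8 ± 1.09 to 17.8 ± 0.699 FPKM (SD, n = 3 each). The focal adhesion genes Vcl and Zyx rose from 153 ± 4.28 to 226 ± 9.33 FPKM and from 47.5 ± 2.24 to 71.4 ± 1.62 FPKM. Tpm4, a tropomyosin, and Cfl1, which severs actin filaments, had log2 fold changes of 0.52 and 0.47. The cytoplasmic actins moved apart, since Actg1 rose from 877 ± 50.7 to 1159 ± 121 FPKM and Actb fell from 1425 ± 81.9 to 1163 ± 31.7 FPKM. The fall of Actb had been seen before this list was tested. Ybx3, a close paralog of Ybx1, was 88.9 ± 7.39 FPKM in siNC and 103 ± 5.16 FPKM in siYBX1 (adjusted p = 0.0421, limma), a call lost in 10 of its alternatives.

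The count of genes past the threshold was set against the other splits of the 6 libraries. Of 10 splits into 3 and 3, only the real 1 reached its 2132 genes, and the highest of the others gave 0. Every other split mixes siNC and siYBX1 libraries, so a group difference of any origin widens the spread within its groups. The 0 is therefore not the count to be had without a group difference. With 10 splits no share under 0.05 can be reached.

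The rise of smooth muscle and myofibroblast genes was weighed first. A lower share of adipocytes in the siYBX1 cultures might raise progenitor markers too. Of 11 tested none rose, 10 had a negative log2 fold change and their median was -0.13, so that the smooth muscle median exceeded it by 1.06. Of 22 general adipocyte genes 2 rose and 3 fell, and without siNC replicate 1 these counts were 2 and 8. The share of adipocytes was not measured, so the lack of a progenitor rise cannot exclude a lower share. Reads shared among actin paralogs cannot account for the rise of smooth muscle genes as a whole, since 5 of 7 members other than actins rose. Control replicate 1 alone cannot, since 7 members rose without it. A candidate explanation is wider activity of serum response factor. Its held-out targets had a median of 0.398 (adjusted p = 4.57e-13, camera), a call lost with an estimated correlation (adjusted p = 0.0602). That list was chosen after the rise had been seen in these same libraries, so it gives no independent support. The held-out YAP and TEAD targets had a median of 0.103 (adjusted p = 0.121, camera), which leaves that explanation open, and whether the siRNA acts through Ybx1 or off target was not tested.

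The rises of ribosomal protein and respiratory chain genes were weighed against gene length, GC content and control replicate 1. GC content as the cause is argued against by medians of 0.171 and 0.208 after its correction. After the length correction the medians were 0.0511 (adjusted p = 0.141, camera) and 0.0748 (adjusted p = 0.0450). Both lie between bounds set before these medians were seen, though the correction itself was chosen after the data were seen. A length trend and a change of these genes therefore cannot be told apart, nor can control replicate 1, without which the medians were 0.121 and 0.114. Against the mean of the 6 libraries the list medians were 0.0065 and -0.0038 in siYBX1 replicate 3, which had almost no length trend (-0.0028), and -0.154 and -0.239 in siNC replicate 1, which had the steepest (-0.154), but the order did not hold throughout, since siYBX1 replicate 2 had a steeper trend than siYBX1 replicate 1 (0.119 against 0.101) and lower list medians (0.103 and 0.0753 against 0.119 and 0.179). The biological explanation, an effect of the knockdown on these transcripts, stays open.

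The fall of G2 and mitosis genes was not removed by the same checks. After the length correction 27 members fell (median -0.395), after the GC correction 26 (median -0.396), and without control replicate 1 25 (median -0.384). These values argue against length, GC content and that library as the whole cause. A lower share of dividing, undifferentiated cells and lower expression per dividing cell were not separated by any test here.

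Igfbp5, Scara5, C3, Timp2 and Fbn1 are expressed by fibroblasts, and a held-out list of 20 fibroblast matrix and complement genes had a median of -0.103, with 3 genes higher and 6 lower (adjusted p = 0.121, camera).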
